A study of Rattus norvegicus with 57 samples.

How the data were processed

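The series measured microRNAs (miRNAs) on 57 one-colour Agilent rat arrays, each hybridised with RNA from 1 sample of nasal epithelium (tissue of the maxilloturbinate), circulating white blood cells or bone marrow cells flushed from the femur. Male Fischer rats had breathed 2 ppm formaldehyde through the nose for 6 hours a day, for 7 days, for 28 days, or for 28 days followed by 7 days of recovery, and control rats sat in the same kind of tube with room air. Each tissue therefore has 6 groups. The labels do not say whether every array came from a different rat, so the errors and p-values describe the spread between these samples.

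Per the file headers, the scanner files hold linear signal intensity for each spot, read by Agilent Feature Extraction in 1 version, with the spot signal already background-subtracted and spatially detrended but not normalized between arrays; some values lie below 0. The raw spot intensity and its local background stand beside it in the same unit. The authors' own value table holds linear intensity as well, is not centred, and was quantile normalized within each tissue and duration. The nasal 28-day and the marrow recovery columns of that table also had a batch effect removed by the authors, and some of them hold values below 0. Partek is the tool named in the processing notes, with no version. The medians of the columns of the authors' table lay between 31.9 and 32.8 in nasal epithelium at 7 days, 28.3 and 29.1 at 28 days, and 30.7 and 30.8 after recovery. The corresponding ranges were 29.6 to 30.7, 22.3 to 22.8 and 35.9 to 37.6 in white blood cells, and 28.8 to 29.1, 24.3 to 24.3 and 30.0 to 31.0 in marrow. The scanner signals were used for the main results because they had been treated alike on every array, and the authors' table served as an alternative.

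Probe signals were the mean over a probe's spots, with control spots and spots marked as outliers left out. A probe counted as detected on an array where more than 50% of its spots were well above background. Each array was scaled to the 75th percentile of the probes detected on all arrays of its tissue, which were 385 probes in nasal epithelium, 365 in white blood cells and 51 in marrow. For the markers of tissues in control rats alone, all 57 arrays were scaled together, to the 75th percentile of probes detected on at least 75% of the arrays. Scaled values under the 5th percentile of the detected signals of the tissue were raised to that floor, the probes of a miRNA were summed, and the sum was put on the log2 scale. The array holds 677 rat miRNAs on 1644 probes. A miRNA was tested where at least 1 probe was detected on every array of at least 1 group of the tissue, which left 324 miRNAs in nasal epithelium, 270 in white blood cells and 215 in marrow.

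The fits used limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 mean per group and all 6 groups of a tissue in 1 fit. There were 9 comparisons of exposed with control arrays and 6 tests of whether the exposure effect differed between durations. A miRNA passed at a two-sided Benjamini-Hochberg adjusted p under 0.05 within its comparison. Log2 fold changes are exposed minus control, and errors of fold changes are standard errors (SE) of the fit. Files were read with numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15 and with the R package for fast tables (data-table, version 1.17.8), and plots were drawn with matplotlib 3.10.9.

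Before the data were examined, 24 lists of miRNA families, genomic clusters and cell type markers were fixed, and 158 of their 164 members matched a miRNA of the array. Their members came from general knowledge of rat miRNAs. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it. Camera compares a list with the other miRNAs. Fry tests whether a list's members move, on balance, one way and does not compare the list with other miRNAs. Some miRNAs stand in more than 1 list, such as miR-34b and miR-9. The miRNAs named in the text follow a rule fixed at the same time. For each comparison these are the 10 largest rises and the 10 largest falls among those past the threshold whose exposed arrays all lie on 1 side of all controls, members of a fixed list that passed, and up to 4 members of a list that did not. Where fewer than 3 passed in a direction, the 3 with the lowest p are named as not passing. For a difference of effects, the 5 largest on each side are named, or the 2 with the lowest p where none passed. A miRNA named in 1 comparison may be followed through the others.

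On simulated data with the spread of these arrays, the fit recovered 25.8%, 58.4% and 95.8% of miRNAs changed 1.5-fold, 2-fold and 4-fold at 7 days in nasal epithelium (324 miRNAs tested). The shares were 48.0%, 87.4% and 99.4% in white blood cells (270 tested) and 0.455%, 1.82% and 55.5% in marrow (215 tested). A raised list was called by camera in 20, 20 and 19 of 20 simulated runs in the respective tissues, and 0 lists that share no member with it were called. The simulated miRNAs were drawn independently of each other, so these runs do not show how camera's preset correlation behaves where miRNAs vary together. The number of arrays limits the precision of every value.

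Whether the replicate numbers of the titles pair exposed with control arrays was checked by correlating arrays of the same number after removal of the group means. Only for nasal epithelium after recovery were all 3 correlations above 0.1, at 0.63, 0.52 and 0.55, with 3 of 3 controls closest to the exposed array of their own number. Elsewhere they were not all above 0.1, though some were of like size (0.59, 0.44 and -0.065 in marrow at 7 days). The main fits therefore hold no term for the replicate number. The arrays lie on 8 slides read in 5 scans. All nasal arrays of 7 days share 1 slide, as do those after recovery. At 28 days nasal control 1 shares a slide with the 3 exposed arrays and nasal controls 2 and 3 lie on another. Each duration of white blood cells lies on 1 slide, with exposed arrays in 1 row and controls in the other, so that row and exposure cannot be told apart there. In marrow after recovery, controls 1 and 2 share a slide, control 3 shares another with exposed 1, and exposed 2 and 3 lie on a further slide read in another scan. Slide and scan are therefore largely tied to exposure in that comparison.

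A total of 20 alternatives were fixed at the same stage as the lists, covering scaling, background, probe summary, detection filter, floor, samples in the fit, slide, scan, replicate number, array weights, the authors' values, thresholds, the set test and the leaving out of each array. A further 4 were chosen after seeing the data: the values rebuilt without arrays that stand apart, the row of the slide as a term, and the normexp background in 2 further forms. Normexp was run in 3 ways in all. The planned run gave nearly no calls, a run fitted by maximum likelihood gave the same counts, and the last run used the median background of each array for every spot. The reason for the last run is that 12 arrays hold spots whose local background exceeds the signal by more than 100, up to 11 on an array, and the same 12 arrays had a lowest normexp signal over 80, up to 995. All runs are reported whatever they gave. A correlation across samples carries a permutation p.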

Results

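The 57 arrays comprised 18 of nasal epithelium, 21 of white blood cells and 18 of bone marrow. Groups held 3 arrays each, except that each exposed group of white blood cells held 4. Of the 13540 miRNA spots on an array, between 4372 and 5795 were well above background in nasal epithelium and between 4167 and 5178 in white blood cells. In marrow the number ran from 593 to 5159, so marrow signals were both weaker and more uneven. Correlations between arrays of a group lay between 0.913 and 0.998 in nasal epithelium, between 0.953 and 0.999 in white blood cells and between 0.744 and 0.973 in marrow, and 0 pairs of arrays were identical.

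The tissues of control rats differed in the markers of their cell types, compared here after all 57 arrays were scaled together rather than within each tissue. The epithelial miR-200b had a mean log2 scaled signal of 5.50 ± 0.78 (SD, n = 9) in nasal epithelium and -6.34 in white blood cells, where 1 of 9 arrays detected it. The ciliated-cell miRNA miR-34b lay at 4.02 ± 0.28 in nasal epithelium against -3.22 ± 0.40 in white blood cells. The red-cell miRNA miR-451 was the reverse, at 0.83 ± 0.45 in nasal epithelium, 7.31 ± 0.27 in white blood cells and 7.33 ± 0.96 in marrow. The granulocyte miRNA miR-223 lay at 0.33 ± 0.21, 5.35 ± 0.24 and 5.16 ± 2.0 in the same order, and the lymphocyte miRNA miR-150 at 4.32 in white blood cells and -0.55 in nasal epithelium. These values were not tested against each other.

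The first question was what inhaled formaldehyde does to miRNAs where it first meets the body. After 7 days the nasal epithelium of exposed rats held more of the miR-183 cluster, which is expressed in sensory epithelia, and of the epithelial miR-200 family (n = 3 exposed and 3 control arrays throughout). miR-183 (chromosome 4, 57075124 to 57075141, rat build rn4, by the probe positions in the files) rose 7.37-fold, a log2 change of 2.88 ± 0.92 (SE, adjusted p = 0.033). miR-96 and miR-182 (chromosome 4, 57071339 to 57071353) of the same cluster rose 5.53-fold and 5.08-fold. In the miR-200 family all 5 tested members rose, among them miR-429 by 1.75 ± 0.34 (adjusted p = 0.0043), miR-200a by 1.57 ± 0.42 and miR-200b (chromosome 5, 172899060 to 172899076) by 1.51 ± 0.40. In each of these the 3 exposed arrays lay above all 3 controls.

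Of 8 neuronal miRNAs 4 rose at 7 days: miR-9 by 1.17 ± 0.15 (adjusted p = 0.00069), miR-9* by 1.22, miR-137 by 1.20 and miR-129 by 0.80. The controls of miR-129 were not above background, so its rise is at least 1.52-fold. Outside the lists, miR-592 rose by 2.00 ± 0.27 and miR-598-3p by 1.73 ± 0.33. The miR-17-92 group, linked to proliferation, rose in 6 of 11 members (7 adjusted over the list alone), by small amounts from 0.22 for miR-106b to 0.86 ± 0.18 for miR-18a.

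Some members of other cell type lists fell at 7 days. The erythroid miR-144 and miR-451 fell 3.51-fold and 3.20-fold, both tested members, and the endothelial miR-126 fell 1.94-fold, 1 of 2 members (2 adjusted over the list alone). Among mesenchymal miRNAs 4 of 9 fell (5 adjusted over the list alone), led by miR-10b at -1.45 ± 0.36 (adjusted p = 0.011), with miR-143, the smooth-muscle miRNA, at -0.82 ± 0.20. The striated-muscle miR-1, miR-133a and miR-133b fell, 3 of 5 members. Of the fixed myeloid list miR-142-5p and miR-223 fell by 1.39 and 0.87 on the log2 scale, 2 of 4 members (3 adjusted over the list alone). That list is not specific to myeloid cells, since miR-142-5p is made in all blood cells. Its member miR-338 lay higher in nasal epithelium of controls (1.30) than in white blood cells (-1.09), with all tissues scaled together. The ciliated-cell list had miR-34c* at -0.94 ± 0.24 and miR-34b at -0.99 ± 0.35, 2 of 5 members (3 adjusted over the list alone), while miR-34c at -1.09 ± 0.44 (adjusted p = 0.083) did not pass. The miR-23/27/24 clusters fell in 5 of 6 members (6 adjusted over the list alone) and the miR-15/16 family in 4 of 6, including miR-503 at -1.33 and miR-322 at -1.21. In the imprinted Dlk1-Dio3 cluster 3 of 17 fell. The inflammation list was split, with miR-146a (-1.22 ± 0.25) and miR-21 (-0.83 ± 0.27) lower and miR-9, which also stands in the neuronal list, higher.

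By camera the miR-200 family (adjusted p = 0.0025), the neuronal list (0.0055), the miR-17-92 group (0.0055) and the miR-183 cluster (0.030) moved up against the other miRNAs. The mesenchymal list (0.0055), the miR-23/27/24 clusters (0.0055), the miR-15/16 family (0.022), the ciliated-cell list (0.041) and the Dlk1-Dio3 cluster (0.041) moved down. None of these calls held with an estimated correlation: adjusted p = 0.20 with an estimated correlation for the neuronal list and adjusted p = 0.41 with an estimated correlation for each of the others. The myeloid list (adjusted p = 0.095) and the muscle list (0.17) missed the threshold. In all, 93 of 324 miRNAs passed at 7 days, 50 higher and 43 lower, and in 187 of the 324 the exposed and control arrays did not overlap, which chance gives in 10% of miRNAs. The count fell to 41 without control 1, 56 without control 3 and 39 without exposed 1, and miR-183 itself passed only with all arrays or without control 2 (adjusted p = 0.16 without control 1). Under quantile normalization the median of the miR-200 family was 0.78 in place of 1.51.

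**Figure D1:**
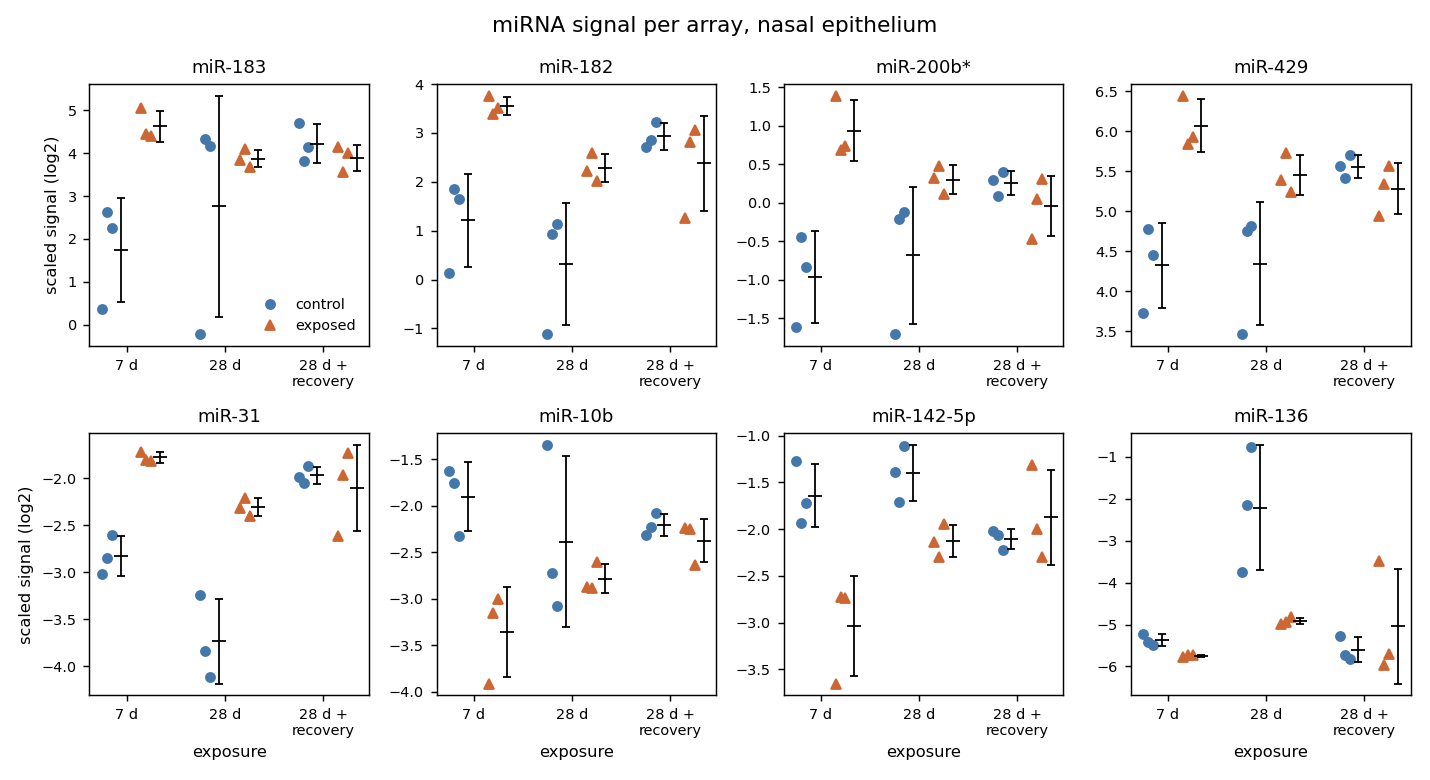
Log2 scaled signal of 8 miRNAs on each nasal array (vertical axes) by exposure (horizontal axes), with controls as circles, exposed arrays as triangles and black bars for mean ± SD (n = 3 per group). At 7 days the exposed arrays of miR-183, miR-182, miR-200b* and miR-429 lie above all controls and those of miR-10b and miR-142-5p below them. At 28 days control 1 of miR-183 (-0.22) lies far below the other controls.

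After 28 days of exposure miR-31 (chromosome 5, 108497682 to 108497697) rose 2.69-fold in nasal epithelium (1.43 ± 0.22, adjusted p = 0.0013, n = 3 and 3). miR-499, a muscle miRNA encoded in a myosin gene, rose by 1.36 ± 0.17 (adjusted p = 0.00046), and miR-425 by 1.24 ± 0.20. The largest falls were in miR-136 (chromosome 6, 134186992 to 134187013), which lies between miR-434 and miR-341 of the Dlk1-Dio3 cluster but was left off the fixed list, at -2.70 ± 0.65 (adjusted p = 0.013), and in the cartilage miRNA miR-140, at -2.23 ± 0.51. miR-21 and miR-223, both higher in inflamed tissue, fell by 1.24 ± 0.27 and 0.90 ± 0.16. In each of these the exposed arrays lay on 1 side of all controls. Their errors and p-values use a spread shared by all 6 nasal groups, and 0 miRNAs passed when only the 28-day arrays were fitted.

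Several of the miRNAs that rose at 7 days passed again at 28 days. Of the miR-183 cluster miR-182 rose by 1.96 ± 0.60 (1 of 3), whereas miR-183 lay at 1.11 ± 0.92 (adjusted p = 0.39). Of the miR-200 family miR-429 rose by 1.11 ± 0.34 and miR-200c by 0.40 ± 0.12 (2 of 5), and of the neuronal list only miR-9, by 0.93 ± 0.15 (1 of 8). The miR-17-92 group rose in 4 of 11 members (5 adjusted over the list alone), the let-7 family in 2 of 8 (4 adjusted over the list alone) with let-7d at 0.61 ± 0.17, and the miR-29 family in 2 of 3. Of the myeloid list miR-142-3p fell with miR-223, 2 of 4 members (3 adjusted over the list alone). In the Dlk1-Dio3 list 4 of 17 fell, among them miR-376a, and miR-494 rose although its groups overlapped. The largest rise, miR-3584-5p at 3.30 ± 0.99, rested on exposed arrays that spread with an SD of 2.8. Neither red-cell miRNA passed at this time (miR-451 at 0.44 ± 0.47, adjusted p = 0.51). No list passed camera at 28 days, where the lowest adjusted p was 0.055 for the myeloid list, and fry passed 3 lists.

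In all 77 miRNAs passed at 28 days, 52 higher (67.5%) and 25 lower. Quantile normalization gave 43.2% higher, scaling over all probes 55.6%, and normexp with the median background of each array 9 higher and 38 lower. Exposed and control arrays did not overlap in 90 of 324 miRNAs, against 10% by chance. Control 1, which shares a slide with the 3 exposed arrays, differed from controls 2 and 3: the 77 miRNAs were shifted by a mean of 0.58 against control 1 and 1.36 against controls 2 and 3, where a single array has an SD of 0.22. On the first principal component of the nasal arrays controls 2 and 3 stood apart, at 16.1 and 19.6, while control 1 lay at 2.13 and every other array at 2.83 or below. On the second component control 1 was the lowest array, at -11. With slide as a fixed term the exposed arrays are compared with control 1 alone, so the count of 41 is not one adjusted for slide with all controls. The 28-day controls varied more than the other nasal groups, with a lowest correlation between arrays of 0.913 against 0.978 or above. Errors at 28 days rest on the spread shared by all 6 nasal groups and may therefore be too small. The count was 29 with slide as a random block and 0 when only these 6 arrays were fitted. It was 181 without control 1, 31 without control 2, 24 without control 3, 28 without exposed 1 and 26 without exposed 2. In the authors' values, from which a batch effect had been removed, 137 passed, 56 higher and 81 lower, and miR-140, miR-33, miR-409-3p, miR-702-3p and miR-2985 no longer lay below control; miR-29a lay at -0.25 (adjusted p = 0.028).

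After 28 days of exposure and 7 days of recovery, the comparison that asks whether changes outlast exposure, 0 of 324 nasal miRNAs passed in limma and 6 had an unadjusted p under 0.05. The lowest p-values belonged to miR-342-3p at -0.41 ± 0.15, miR-770* at 0.53 ± 0.22 and miR-132 at -0.51 ± 0.23, none of which passed (adjusted p = 1.0 for each, n = 3 and 3). miR-183 lay at -0.33 ± 0.92, miR-429 at -0.27 ± 0.34 and miR-144 at 1.17 ± 0.52. Exposed and control arrays did not overlap in 40 of 324 miRNAs, or 12.3%, against 10% by chance. By camera the lymphoid list (adjusted p = 0.014, median -0.20), the miR-17-92 group (0.025, median -0.17) and the let-7 family (0.029, median -0.23) moved down and the ciliated-cell list moved up (0.029, median 0.19), though 0 of their members passed. Each had adjusted p = 0.82 with an estimated correlation, and fry passed none. With the replicate number as a block only the lymphoid list and the miR-17-92 group passed (adjusted p = 0.023 for both).

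The change in effect was tested directly. Every nasal difference here holds the 28-day comparison, whose controls 2 and 3 lie on another slide than the exposed arrays. Slide is therefore not fully separated from exposure in these differences. From 28 days to recovery 33 nasal miRNAs differed in their exposure effect, 10 with a positive and 23 with a negative difference (30.3% positive, against 38.5% of 13 under quantile normalization and 42.9% of 14 under scaling over all probes). The effect on miR-136 differed by 3.26 ± 0.91 (adjusted p = 0.042), on miR-142-3p by 2.10 ± 0.60, on miR-21 by 1.51 ± 0.38, on miR-31 by -1.56 ± 0.32 and on miR-499 by -1.45 ± 0.24 (adjusted p = 0.0033). With the replicate number as a block, 6 passed, all with a negative difference, among them miR-31 and miR-499, while miR-136, miR-142-3p and miR-21 did not (adjusted p = 0.073, 0.073 and 0.078). The block pairs the arrays of every duration by number, although at 28 days the correlations by number were only 0.054, 0.20 and -0.084. The lower count can therefore not be put down to pairing of the recovery arrays alone. For this step 18 miRNAs passed with slide as a random block and 4 when only the groups compared were fitted. The median difference of all miRNAs was -0.145, and 0.127 for the step from 7 to 28 days. The myeloid list moved up by camera (adjusted p = 0.035, adjusted p = 0.72 with an estimated correlation, fry 0.036), with 2 of 4 members past the threshold (3 adjusted over the list alone). The count was 153 without the 28-day control 1, 13 without control 2, 10 without control 3, 6 without exposed 1 or 2 and 9 without exposed 3 of 28 days, and among the recovery arrays 6 without control 1, 9 without control 2 or 3 and 6 without exposed 1. Between 7 and 28 days 0 nasal miRNAs differed in limma, 102 had an unadjusted p under 0.05 and the lowest adjusted p was 0.11, for miR-382 (higher) and miR-344a-3p (lower), whose sizes were partly set by arrays at the floor; without the 28-day control 1 the count was 183, without 7-day exposed 2 it was 2 and without 28-day exposed 2 it was 1. Camera put the miR-200 family down and the mesenchymal list up between these durations (adjusted p = 0.031 for both, adjusted p = 0.63 with an estimated correlation).

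Formaldehyde reacts at the site of entry, and the arrays of blood and marrow address whether miRNAs change in cells away from it. In white blood cells after 7 days the largest rises were in miR-33, encoded in a gene of sterol regulation, by 1.54 ± 0.24 (2.91-fold, adjusted p = 0.00097, n = 4 exposed and 3 control arrays) and in miR-32 by 1.11 ± 0.20. miR-142-5p, made in all blood cells, rose by 0.82 ± 0.20, miR-29b by 0.73 ± 0.12, miR-141 by 0.69 ± 0.087 and miR-326 (chromosome 1, 156887577 to 156887592) by 0.67 ± 0.19. The largest falls were in miR-1224 at -1.57 ± 0.44 and miR-188 at -1.32 ± 0.30. The red-cell miRNA miR-451 (chromosome 10, 64129536 to 64129555) fell by 0.94 ± 0.25 (adjusted p = 0.028), while miR-144 lay at 0.45 ± 0.55 and did not pass. All 4 exposed arrays lay on 1 side of all 3 controls in each miRNA that is named as having risen or fallen.

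Members of the fixed lists that passed in blood at 7 days included miR-29b, miR-141 and miR-451. Of the myeloid list 1 of 5 members rose (3 adjusted over the list alone), and 0 of 7 of the lymphoid list passed. In the Dlk1-Dio3 cluster 1 of 4 fell, miR-487b (3 adjusted over the list alone). No list passed camera, with a lowest adjusted p of 0.16 for the myeloid and Dlk1-Dio3 lists, which both passed fry. In all 26 of 270 miRNAs passed, 13 higher and 13 lower, and 90 had an unadjusted p under 0.05. Groups did not overlap in 124 miRNAs, against 5.71% by chance. The balance depended on the processing and turned both ways: 50% were higher in the main scaling, 75% of 32 under quantile normalization and 93.1% of 72 with scaling over all probes, which shifted the median of all miRNAs by 0.45. Normexp with the median background of each array gave 8 higher of 133, and the values rebuilt without arrays that stand apart 15 higher and 42 lower; both were chosen after seeing the data. The count was 7 without control 2, exposed 2 or exposed 4, 11 without exposed 1 and 13 without control 3.

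After 28 days the lymphocyte miRNA miR-150 (chromosome 1, 95596098 to 95596113) was 2.65-fold lower in white blood cells of exposed rats (-1.40 ± 0.27, adjusted p = 0.0021, n = 4 and 3). miR-342-3p and miR-342-5p, also markers of lymphocytes, fell by 0.83 ± 0.21 and 1.01 ± 0.21, so that 3 of 7 lymphoid miRNAs fell while miR-181d rose by 0.53 ± 0.12. The endothelial miR-126 and miR-126* rose by 0.76 ± 0.13 and 0.51 ± 0.11, both tested members, and the hypoxia miRNA miR-210 by 0.70 ± 0.13. The largest changes were a rise of miR-383 by 1.59 ± 0.25 (adjusted p = 0.0009) and a fall of miR-1949 by 1.79 ± 0.37. The red-cell miR-451 fell again, by 0.68 ± 0.25 (adjusted p = 0.044), and missed the threshold under quantile normalization (adjusted p = 0.098).

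Some members of several miRNA families passed in blood at 28 days, with small changes, where 34.4% of all miRNAs passed. The miR-17-92 group rose in 6 of 11 members (6 adjusted over the list alone), by 0.26 for miR-19a to 0.43 ± 0.11 for miR-92a, although miR-19a lay at -0.006 under quantile normalization. The miR-23/27/24 clusters rose in 3 of 6 (4 adjusted over the list alone), among them miR-24 by 0.50 ± 0.099, and the let-7 family in 3 of 8 (5 adjusted over the list alone), among them let-7i by 0.38 ± 0.10. In miR-19a, miR-92a and let-7i the arrays of the groups overlapped. Of the p53-associated miRNAs miR-192 and miR-194 fell, 2 of 5. miR-326 and miR-32, which had risen at 7 days, passed again at 0.82 ± 0.19 and 0.68 ± 0.20. No list passed camera (lowest adjusted p = 0.11, for let-7) and fry passed 4 lists. The median of the lymphoid list was -0.27, and 0.15 with scaling over all probes, under which miR-150 still passed (-0.98, adjusted p = 0.044) and the miR-342 arms did not.

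In all 93 of 270 miRNAs passed in blood at 28 days, 54 higher (58.1%) and 39 lower, and 80 did not overlap between groups, against 5.71% by chance. Quantile normalization gave 68.9% higher and scaling over all probes 92.3%, with a shift of 0.28 in the median of all miRNAs. The values rebuilt without arrays that stand apart gave 38 higher and 53 lower, so the balance turned both ways. The count was 56 without control 3 and 34 when only these 7 arrays were fitted.

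**Figure D2:**
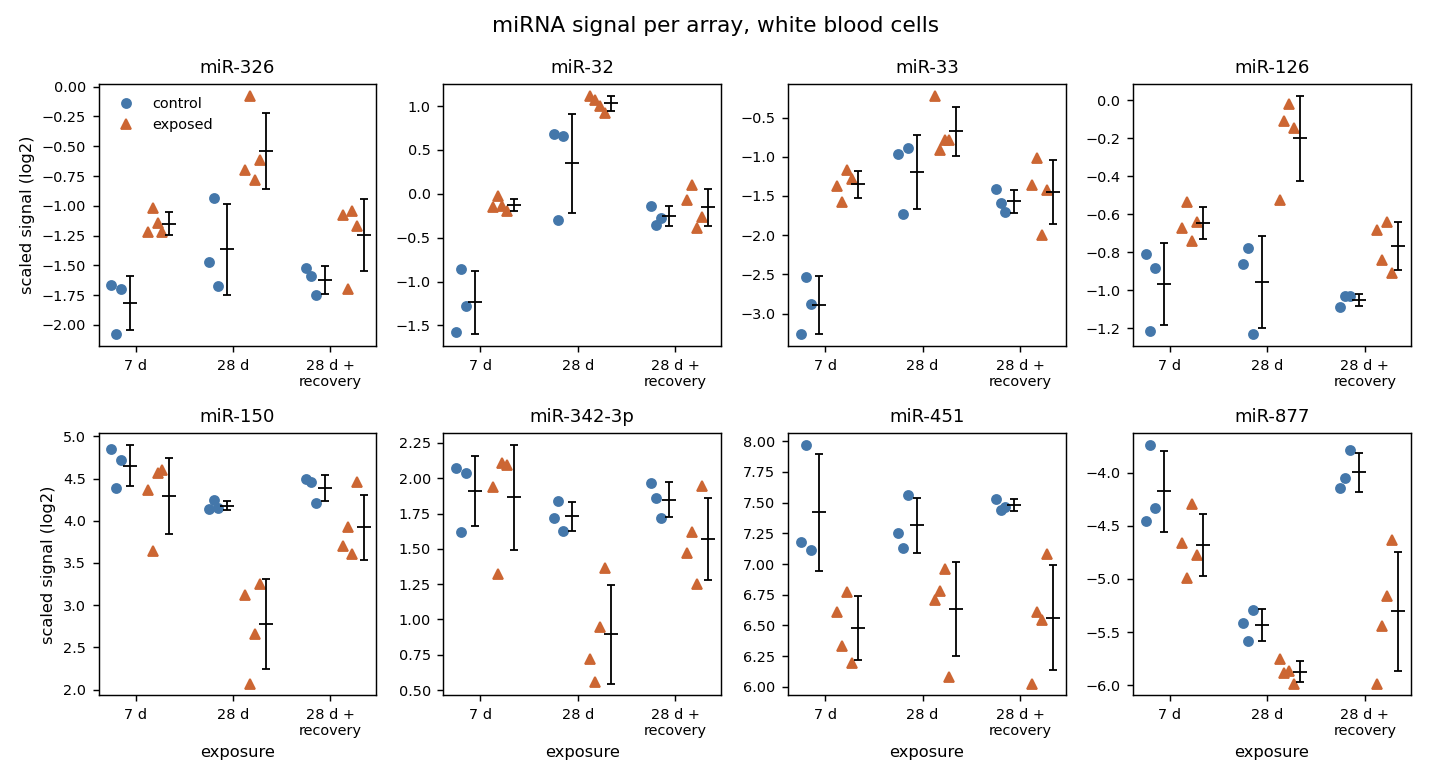
Log2 scaled signal of 8 miRNAs on each array of white blood cells (vertical axes) by exposure (horizontal axes), with controls as circles (n = 3 per group), exposed arrays as triangles (n = 4) and black bars for mean ± SD. miR-326, miR-32 and miR-126 lie higher and miR-150, miR-342-3p and miR-451 lower in exposed arrays at 28 days in this scaling. miR-877 is lower in exposed arrays after recovery.

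After recovery 1 miRNA of white blood cells passed: miR-877 (chromosome 20, 2958192 to 2958203) was 2.48-fold lower in exposed rats (-1.31 ± 0.24, adjusted p = 0.014, n = 4 and 3), with all exposed arrays below all controls. miR-451 lay at -0.91 ± 0.25 (adjusted p = 0.089), miR-25 at -0.49 ± 0.13 (0.089) and miR-143 at 0.39 ± 0.11 (0.097), and none of these passed. Nor did miR-376b-3p (adjusted p = 0.089), lower in exposed rats with 3 of 4 exposed arrays at the floor, so that its size was not measured; its sign turned under the planned normexp background (0.26). In miR-877 1 exposed array was at the floor. miR-150 lay at -0.47 ± 0.27 (adjusted p = 0.33). An unadjusted p under 0.05 was found for 62 miRNAs, and 68 of 270 did not overlap, against 5.71% by chance. The count was 22 without exposed 4 and 0 without control 2, control 3 or exposed 2. miR-877 missed the threshold with scaling over all probes (-0.99, adjusted p = 0.15) and lay at 0.027 (adjusted p = 0.99) with the planned normexp background.

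No difference of effects passed in blood by limma: 0 miRNAs from 7 to 28 days (45 with an unadjusted p under 0.05) and 0 from 28 days to recovery (40). The lowest adjusted p-values were 0.16 for miR-1912-3p and miR-26a (0.37 ± 0.10) and, for the later step, 0.19 for miR-1912-3p and miR-151* (-0.84 ± 0.25). miR-1912-3p lay at the floor on most arrays of 7 days and recovery, so the size of its difference was not measured, and without the floor it lay at -0.28 for the later step. Without exposed 1 of 28 days the counts were 26 and 24, and without 7-day control 1 the earlier count was 1. Scaling over all probes shifted the median difference of the later step by -0.39. From 7 to 28 days camera put the miR-17-92 group (adjusted p = 0.010) and the let-7 family (0.029) up and the lymphoid list (0.029) down, each with adjusted p = 0.58 with an estimated correlation. From 28 days to recovery it put let-7 and the miR-17-92 group down (adjusted p = 0.015 for both, adjusted p = 0.85 with an estimated correlation).

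In bone marrow, where blood cells are made, 0 of 215 miRNAs passed at 7 days, 28 days or after recovery in limma, with 7, 0 and 53 at an unadjusted p under 0.05. At 7 days miR-150 lay at 2.04 ± 0.74 and miR-196b at -1.97 ± 0.83 (adjusted p = 0.95 for both, n = 3 and 3). At 28 days the lowest p belonged to miR-107 at 1.02 ± 0.49 and miR-374 at 0.88 ± 0.44 (adjusted p = 1.0 for both). After recovery miR-30e* was lower, with exposed 3 at the floor so that its size was not measured, while miR-146a lay at -1.63 ± 0.54 and let-7b at 1.53 ± 0.55 (adjusted p = 0.20 for each). Exposed 2 and 3 of this group lay on another slide and scan than the controls, so these values do not separate exposure from slide. The median of all miRNAs was -0.11, 0.22 and -0.36 at the 3 times, and 0.027 or nearer to 0 under quantile normalization, so these values are to be read relative to that shift. Groups did not overlap in 22, 13 and 42 of 215 miRNAs, against 10% by chance.

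At 28 days in marrow camera put the miR-15/16 family (median 0.98) up (adjusted p = 0.024) and the inflammation list up (0.043). It put the let-7 family (median -0.23) and the muscle list down (0.024 for both). In these lists 0 members passed the threshold, each had adjusted p = 0.46 with an estimated correlation, and fry passed none. The medians of the miR-15/16 and let-7 families depended on 28-day control 1. There miR-15b (-2.80), miR-16 (1.60), miR-195 (-7.40) and let-7d (-0.53) lay below all other 28-day marrow arrays on the log2 scale. Above all others lay let-7a (2.31), let-7f (2.425) and let-7i (1.93) of that array. Without recovery exposed 1 the count after recovery was 15, but the exposed arrays then shared no slide or scan with the controls. No difference of effects passed by limma in marrow: 0 from 7 to 28 days and 0 from 28 days to recovery, with 3 and 27 at an unadjusted p under 0.05. The lowest adjusted p was 0.33 for miR-374 (lower, with 2 exposed recovery arrays at the floor) and miR-146a (-2.26 ± 0.76), both for the later step, and 0.99 for miR-146b (1.39 ± 0.55) for the earlier one; without recovery exposed 1 the later count was 1. The median difference of all marrow miRNAs was 0.33 for the earlier step and -0.63 for the later, against 0.0054 and -0.091 under quantile normalization. Exposed 3 of the recovery group had 593 spots well above background, the fewest of all arrays.

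Across miRNAs, which are not independent replicates, the effects at 7 and 28 days had a Pearson correlation of 0.70 in white blood cells, with a leave-one-out standard error of 0.11, and 0.26 ± 0.34 in nasal epithelium. In nasal epithelium 25 miRNAs rose at both times, against 8.02 by chance, 6 fell at both, against 3.32, and 0 passed in opposite directions, against 10.8. In white blood cells 9 rose at both times, against 2.60 by chance, and 4 fell at both, against 1.88. At every duration exposed arrays of white blood cells lay in 1 row of the slide and controls in the other. An effect of row that recurs would also give such agreement, so these values do not separate exposure from row. The effect after recovery had a correlation of -0.32 ± 0.22 with that at 7 days and -0.30 ± 0.59 with that at 28 days in nasal epithelium. The corresponding values were 0.26 ± 0.60 and 0.48 ± 0.43 in white blood cells, and 0.59 and 0.72 over miRNAs detected on every array. In marrow the 3 correlations were 0.13, 0.062 and -0.28, each with an error of at least 0.48, and over miRNAs detected on every array they were 0.46, -0.078 and -0.29. Whether effects differed between tissues was not tested.

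The counts also depended on array weights and on the background. With array weights 161 nasal miRNAs passed at 7 days and 202 at 28 days, with 200 for the difference between these times and 184 for that between 28 days and recovery. In white blood cells weights gave 106 at 7 days and 98 and 30 for the respective differences. With the planned normexp background 2 nasal miRNAs passed at 7 days and 0 at 28 days, and 0 and 6 in white blood cells; a maximum likelihood fit gave the same counts. Normexp with the median background of each array, chosen after seeing these, gave 20 and 47 in nasal epithelium and 133 and 42 in white blood cells at the same times, and 0 in white blood cells after recovery, where miR-877 lay at -0.73. Under the planned normexp the median standard error of a fold change was 0.58 in nasal epithelium, against 0.23 in the main fit.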

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

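The counts over other splits of the arrays, the test of place on the slide and the test of the ciliated-cell list were chosen after the results were seen; the predictions for sensory mucosa, the slide and lymphocytes were written after the patterns were seen but before these tests were run.

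The nasal pattern at 7 days sets rises in the miR-200 family, the miR-183 cluster and some neuronal miRNAs against falls of some ciliated, erythroid and mesenchymal ones. The ciliated-cell list had a mean log2 change of -0.79, so the epithelial lists did not all rise together. That fall is itself part of the pattern, so it is no separate test of a larger share of epithelium of every kind in exposed samples. A place effect that recurs on both slides is argued against for the 93 called miRNAs. They moved by -0.1 of their 7-day shift on the recovery slide, which has the same layout (limits -0.44 to 0.23). The limits hold no spread between slides. A place effect of the 7-day slide alone cannot be told apart from exposure by this ratio. A larger share of sensory (olfactory) mucosa in exposed samples remains a candidate explanation: over the 12 nasal arrays of the other durations, with group means removed, the neuronal and sensory miRNAs went with the miR-200 family at r = 0.89, over the 0.5 written down before the test (permutation p = 0.0041, adjusted 0.012; rho = 0.91, permutation p = 0.0047, adjusted 0.014), 0.83 without the 2 farthest arrays and 0.86 within the recovery slide of 6 arrays, while their relation to the ciliated-cell list was -0.097 (permutation p = 0.86, adjusted 0.86; rho = -0.19, permutation p = 0.67, adjusted 0.67), -0.74 without the 2 farthest and -0.84 within that slide. That relation may reflect where the tissue was taken or a change in the mucosa under formaldehyde, which these arrays do not separate, and 3 such relations were computed in all.

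The nasal changes at 28 days may in part come from the slides. Against control 1, which shares the slide of the exposed arrays, the 77 called miRNAs shifted by 0.43 of their shift against controls 2 and 3, between the bounds written before that test for and against the slide. These miRNAs were called with control 1 among the controls and the same exposed arrays enter both shifts, so the ratio is partly set by that selection. With 1 control on the slide of the exposed arrays, the slide cannot be told apart from a difference between control samples, and an effect of formaldehyde remains open and untested beside it.

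The pattern in white blood cells at 28 days, with lower miR-150 and miR-342 arms and 93 called miRNAs, could come from place on the slide, since exposed arrays fill 1 row and controls the other. On the recovery slide of the same layout the called miRNAs moved by 0.41 of their 28-day shift (limits 0.12 to 0.70), which does not decide for or against place. Fewer lymphocytes among the cells is a candidate explanation: over the 14 arrays of the other durations the lymphoid score went with that of the other called miRNAs at r = -0.71 (permutation p = 0.042, adjusted 0.063; rho = -0.63, permutation p = 0.048, adjusted 0.073), and at -0.51 and -0.98 within the 7-day and recovery slides of 7 arrays each. Without the 2 farthest arrays r was -0.37, so the relation rests on those arrays and fails the correction. The -0.98 includes exposed 1 of recovery, whose median signal was 13.0 against 1.39 to 1.65 on the other exposed arrays. That value may therefore rest on this array. In controls with all tissues scaled together, the 3 miRNAs of the lymphoid score lay at 4.32 (miR-150), 1.74 (miR-342-3p) and -2.46 (miR-342-5p) on the log2 scale. The cell preparation keeps lymphocytes.

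The counts were compared with those from other splits of the same arrays. The 26 miRNAs of white blood cells at 7 days were reached by 1 of 35 splits, the real one, with 2 the highest of the others, which argues against chance in the grouping at that share. The share is not corrected for the other comparisons. The real split is also the split by row of the slide, so this count does not separate exposure from row. The count of 33 nasal miRNAs whose effect differed between recovery and 28 days was reached by 1 of 100 splits with 23 the highest other. Those splits did not keep the number pairs of the recovery arrays, and the replicate block, which also pairs the 28-day arrays, gave a count of 6, so chance was not excluded for that count. Chance cannot be excluded for the 93 miRNAs of white blood cells at 28 days, reached by 2 of 35 splits, because grouping exposed 1 with the 3 controls gave 110. Nor can it be for the 1 miRNA after recovery, reached by 3 of 35 splits, where grouping exposed 4 with the controls gave 23.

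For 3 arrays against 3 the 10 splits are too few for a share under 0.05. The nasal count at 7 days was 93 in 1 of 10 splits, with 0 the highest other. At 28 days it was 77 in 1 of 10 splits, with 55 the highest other, from the split that put controls 2 and 3 of the other slide with exposed 2. After recovery the real count was 0 and the highest other 1, so that 10 of 10 splits gave as many, and the split with 1 parted only 1 of the 3 pairs that share a number. In marrow 10 of 10 splits gave at least the real count of 0 at each duration, with 0, 2 and 20 as the highest others. For differences of effects with a real count of 0, 100 of 100 splits gave as many, with highest others of 95 in nasal epithelium, 49 and 93 in white blood cells and 3 and 15 in marrow. A split that exchanges exposed and control arrays within 1 duration adds the exposure effects, so these counts do not separate exposure from other structure.

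The following single results stood out. A total of 82 groups of 4 exposed arrays of white blood cells were tested for an array far from the rest, and 7 of them (8.5%) had one, where chance gives about 1 in 20. At 28 days exposed 1 was the lowest for let-7e (gap of 0.888 of the range), miR-10a-5p (0.884), miR-322 (0.850) and miR-338 (0.901). At 7 days exposed 4 was the lowest for miR-331 (0.881). After recovery exposed 4 was the highest for miR-376b-3p (1 of the range), as the other arrays were all at -6.99, and exposed 1 had a median signal of 13.0 against 1.39 to 1.65 (0.978). The exposure effect in nasal epithelium differed between recovery and 28 days, by the test of the difference itself, for 33 miRNAs in the fit without the replicate block and for 6, all negative, with it. The positive differences named here lost their call with the block and the negative ones kept it. That block also pairs the 28-day arrays, whose correlations by number were not all above 0.1. The difference also holds the split of the 28-day controls over slides. The 33 include miR-136 (3.26), miR-142-3p (2.10), miR-144* (1.67), miR-21 (1.51), miR-376a (1.36), miR-425 (-1.57), miR-31 (-1.56), miR-499 (-1.45), miR-340-5p (-1.32) and miR-7a-1* (-1.23). Effects in different tissues were not tested against each other.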

How the results depend on the processing

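The normexp forms, the row of the slide and the values rebuilt without arrays that stand apart were chosen after seeing the data; the other alternatives were fixed before. Of the 173 called named results, 139 of 173 kept their call under quantile normalization, 131 of 173 under scaling over all probes, 139 of 173 with slide as a fixed term, 170 of 173 with the mean of log2 probes, 106 of 163 in the authors' values, 7 of 173 under the planned normexp and 79 of 173 under its last form. By comparison 75.9% of outcomes were unchanged for nasal 7 days, 54% for nasal 28 days, 59.1% for nasal recovery minus 28 days, 64.8%, 74.3% and 56% for blood at the 3 times. Scaling over all probes was not run for marrow, and the row of the slide could not be separated from exposure in blood. Each blood duration has a slide of its own, so slide and scan terms could change no blood call, and these calls are among the 139. They also count as unchanged in the blood shares. An adjusted p under 0.1 keeps every call by construction and counts as unchanged in the shares of all comparisons. For nasal 28 days slide and scan terms, like the values rebuilt without controls 2 and 3, compare the exposed arrays with control 1 alone. The array weights did not converge in all fits. Blood stands for white blood cells here. The main counts were 93 (nasal 7 days), 77 (nasal 28 days), 33 (nasal recovery minus 28 days), 26 (blood 7 days), 93 (blood 28 days), 1 (blood recovery) and 0 in every other comparison.

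The following values turned sign or moved a count by over 1.5 times, and the cause was not tested. Scaling over all probes gave counts of 14 (nasal recovery minus 28 days), 72 (blood 7 days) and 0 (blood recovery). miR-203 lay at 0.012, miR-30b-5p at 0.14 and miR-30c at 0.017 (blood 28 days), miR-93 at 0.074 (blood 7 days) in that setting. An adjusted p under 0.1 gave counts of 122 (nasal 28 days), 58 (nasal recovery minus 28 days), 64 (blood 7 days) and 9 (blood recovery). Array weights gave counts of 161 (nasal 7 days), 202 (nasal 28 days), 200 (nasal 28 minus 7 days), 184 (nasal recovery minus 28 days), 106 (blood 7 days) and 98 (blood 28 minus 7 days). It also gave 30 (blood recovery minus 28 days) and 1 (marrow recovery minus 28 days). miR-874 lay at 0.066 (marrow 28 days) in that setting. The authors' values gave counts of 137 (nasal 28 days), 87 (blood 7 days), 42 (blood 28 days) and 0 (blood recovery). miR-7a-1* lay at -0.29 (marrow 7 days), miR-30e* at 0.16 (marrow recovery), miR-140 at 0.34, miR-33 at 0.15, miR-2985 at 0.087, miR-702-3p at 0.14, miR-409-3p at 0.018 and miR-29a at -0.25 (nasal 28 days) in that setting. Camera with an estimated correlation passed 0 (nasal 7 days), 0 (nasal recovery), 0 (nasal 28 minus 7 days), 0 (nasal recovery minus 28 days), 0 (blood 28 minus 7 days), 0 (blood recovery minus 28 days) and 0 (marrow 28 days) lists. Keeping miRNAs detected on every array gave counts of 17 (blood 7 days) and 0 (blood recovery). Fry passed 3 (nasal 28 days), 0 (nasal recovery), 0 (nasal 28 minus 7 days), 3 (nasal recovery minus 28 days), 2 (blood 7 days), 4 (blood 28 days) and 0 (blood recovery minus 28 days) lists. Lists past its threshold numbered 0 (marrow 28 days). No detection filter gave counts of 45 (nasal 28 days), 1 (nasal 28 minus 7 days), 12 (nasal recovery minus 28 days), 10 (blood 7 days), 58 (blood 28 days) and 0 (blood recovery). It also gave 2 (blood 28 minus 7 days), 1 (marrow recovery) and 1 (marrow recovery minus 28 days). No floor gave counts of 9 (nasal recovery minus 28 days) and 0 (blood recovery). miR-1912-3p lay at -0.28 (blood recovery minus 28 days) in that setting. The planned normexp background gave counts of 2 (nasal 7 days), 0 (nasal 28 days), 0 (nasal recovery minus 28 days), 0 (blood 7 days), 6 (blood 28 days) and 0 (blood recovery). miR-499 lay at -0.12 (blood 28 days), miR-877 at 0.027 and miR-376b-3p at 0.26 (blood recovery), miR-151* at 0.45 (blood recovery minus 28 days) in that setting. miR-125b* lay at 0.092 (marrow 28 days), miR-7a-1* at -1.17 (marrow 7 days), miR-30e* at 1.15 and miR-374 at 1.33 (marrow recovery). miR-374 lay at 0.89 (marrow recovery minus 28 days), miR-423* at -0.33 (nasal 28 days), miR-382 at -0.56 (nasal 28 minus 7 days). miR-300-3p lay at 0.022 and miR-382 at 0.049 (nasal 7 days), miR-342-3p at 0.099, miR-132 at 0.45 and miR-505* at 0.88 (nasal recovery), miR-31 at 0.086, miR-499 at 0.27, miR-340-5p at 0.12 and miR-7a-1* at 0.73 (nasal recovery minus 28 days). Normexp fitted by maximum likelihood gave counts of 2 (nasal 7 days), 0 (nasal 28 days), 0 (nasal recovery minus 28 days), 0 (blood 7 days), 6 (blood 28 days) and 0 (blood recovery). miR-499 lay at -0.12 (blood 28 days), miR-877 at 0.034 and miR-376b-3p at 0.27 (blood recovery), miR-151* at 0.46 (blood recovery minus 28 days) in that setting. miR-125b* lay at 0.10 (marrow 28 days), miR-7a-1* at -1.17 (marrow 7 days), miR-30e* at 1.16 and miR-374 at 1.34 (marrow recovery). miR-374 lay at 0.89 (marrow recovery minus 28 days), miR-96* at -0.0086 and miR-423* at -0.35 (nasal 28 days), miR-382 at -0.56 (nasal 28 minus 7 days). miR-300-3p lay at 0.0046 and miR-382 at 0.032 (nasal 7 days), miR-342-3p at 0.11, miR-132 at 0.46 and miR-505* at 0.89 (nasal recovery), miR-31 at 0.11, miR-499 at 0.29, miR-340-5p at 0.14 and miR-7a-1* at 0.76 (nasal recovery minus 28 days). Normexp with the array's median background gave counts of 20 (nasal 7 days), 47 (nasal 28 days), 0 (nasal recovery minus 28 days), 133 (blood 7 days), 42 (blood 28 days) and 0 (blood recovery). miR-499 lay at -0.12 (blood 28 days), miR-1912-3p at 0.34 (blood 28 minus 7 days), miR-542-3p at -0.46, miR-450a at -0.21 and miR-499 at -0.71 (blood 7 days) in that setting. miR-499 lay at -0.32 and miR-199a-3p at -0.12 (blood recovery), miR-125b* at 0.22 (marrow 28 days), miR-7a-1* at -2.53 (marrow 7 days). miR-30e* lay at 0.74 and miR-374 at 0.92 (marrow recovery), miR-374 at 0.34 (marrow recovery minus 28 days), miR-423* at -0.23 (nasal 28 days). miR-382 lay at -0.52 (nasal 28 minus 7 days). Fitting only the groups compared gave counts of 0 (nasal 28 days), 4 (nasal recovery minus 28 days), 42 (blood 7 days), 34 (blood 28 days), 0 (blood recovery) and 2 (blood 28 minus 7 days). Quantile normalization gave counts of 13 (nasal recovery minus 28 days) and 2 (blood recovery). miR-19a lay at -0.006 (blood 28 days) in that setting. Leaving out the arrays that stand apart gave counts of 4 (nasal 28 minus 7 days), 57 (blood 7 days) and 2 (blood 28 minus 7 days). The similarity of effects between durations over miRNAs detected on every array was 0.59 for blood 7 days with recovery, 0.72 for blood 28 days with recovery, 0.46 for marrow 7 with 28 days and -0.078 for marrow 7 days with recovery, and 0.083 for marrow 7 with 28 days under quantile normalization. The replicate block gave counts of 6 (nasal recovery minus 28 days), 9 (blood 7 days), 59 (blood 28 days) and 27 (marrow recovery). Lists past its threshold numbered 2 (nasal recovery), 1 (blood 28 minus 7 days), 0 (blood recovery minus 28 days) and 2 (marrow 28 days). Row as a fixed term gave counts of 25 (nasal 28 days) and 67 (nasal recovery minus 28 days). Scan as a fixed term gave counts of 41 (nasal 28 days) and 2 (nasal 28 minus 7 days). miR-93 lay at -0.010 (nasal 28 days) in that setting. Slide as a fixed term gave counts of 41 (nasal 28 days) and 2 (nasal 28 minus 7 days). miR-99a lay at -0.060 (marrow recovery), miR-93 at -0.010 (nasal 28 days) in that setting. Slide as a random block gave counts of 29 (nasal 28 days), 1 (nasal 28 minus 7 days) and 18 (nasal recovery minus 28 days). An unadjusted p under 0.05 with 1.5-fold gave counts of 1 (nasal recovery), 82 (nasal 28 minus 7 days), 84 (nasal recovery minus 28 days), 46 (blood 7 days), 54 (blood 28 days) and 16 (blood recovery). It also gave 18 (blood 28 minus 7 days), 16 (blood recovery minus 28 days), 7 (marrow 7 days), 53 (marrow recovery), 3 (marrow 28 minus 7 days) and 27 (marrow recovery minus 28 days).

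Leaving out each array in turn gave counts of 39 to 89 (nasal 7 days), 24 to 181 (nasal 28 days), 0 to 183 (nasal 28 minus 7 days) and 6 to 153 (nasal recovery minus 28 days). In blood the ranges were 7 to 30 (7 days), 56 to 129 (28 days), 0 to 22 (recovery), 0 to 26 (28 minus 7 days) and 0 to 24 (recovery minus 28 days). In marrow they were 0 to 15 (recovery) and 0 to 1 (recovery minus 28 days), and 0 to 0 elsewhere. Without marrow 28-day control 1, miR-874 lay at 0.13 and miR-188 at 0.34, both below control in the main fit; over all left-out arrays their lowest values were -1.24 and -2.31. For nasal recovery all 3 correlations by number were above 0.1, but whether the numbers pair the samples is not known. There the replicate block changed only the calls of the let-7 and ciliated-cell lists in the comparison of exposed with control.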

Other observations

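In nasal epithelium at 7 days miR-183* rose by 2.60 ± 0.58, miR-96* by 2.00 ± 0.43, miR-200b* by 1.91 ± 0.39 and miR-200a* by 1.61 ± 0.28. At 28 days miR-183* and miR-96* rose again, by 1.81 and 1.54, and miR-598-3p by 1.17 ± 0.33. The muscle miR-206 fell by 1.44 ± 0.42 at 28 days while miR-499 of the same list rose.

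In white blood cells at 28 days the epithelial miR-141, which is rare in blood cells, rose by 0.31 after a rise of 0.69 at 7 days. The mesenchymal miR-143 and miR-199a-3p rose by 0.70 ± 0.11 and 0.73 ± 0.16, 2 of 7 members of their list, whose median was 0.036 and whose mean was -0.053. miR-499 rose at both times, by 0.25 and 0.48, and lay at -0.12 at 28 days under the planned normexp background.

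Where a called miRNA had at least 2 detected probes, 0 had probes of opposite sign among 62 at 7 days and 57 at 28 days in nasal epithelium and among 21 and 82 in white blood cells. Marrow after recovery held between 593 and 3130 spots well above background in exposed arrays and between 1798 and 4322 in controls. The number of saturated spots was 0 on every array.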
